A study of Mus musculus with 24 samples.

How the data were processed

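RNA of flow-sorted bone marrow populations was measured in 24 mouse libraries prepared by Smart-seq2 after PicoPure extraction; per the labels, the mice received tamoxifen on 5 days and were sorted 12 weeks later. The deposited table holds raw counts per Entrez gene as the authors made them; per the submitters' processing notes the tools were STAR 2.7.0c, featureCounts and Subread 1.6.4 on mm10, with the annotation, strand setting and handling of multiply mapped reads not stated. A further column, the gene length in bases as deposited, was used as a length in bases and not as a measurement. The table has 24454 genes, of which 24374 were matched by ID to RefSeq genes of GRCm38.p6, the assembly behind mm10, for coordinates. Rows without a symbol numbered 16 and held at most 0.013% of the counts of a library. The columns of 18 libraries match their sample titles, and 6 columns named MEP were taken as the 6 preMegE libraries by genotype and replicate number; 0 value columns were left unmapped. Each library was 1 column and none of the 276 pairs of libraries was a copy (smallest chi-square per degree of freedom 20.69).

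Samples were grouped by population and genotype from the titles, 3 libraries in each of 8 groups. Total counts were 10357877 to 29691635 per library, and the spread between replicates, not counting error, set the precision. Reads of Smart-seq2 carry no molecular identifiers, so counts are not independent molecules. Hba-a1 and Hba-a2, Hbb-bs and Hbb-b1, and Hbb-bt and Hbb-b2 are near copies whose reads cannot be told apart in a count table, so a change in both members of a pair was read as a change of 1 locus. The list tests and counts still take each globin gene as 1 member, so they count such reads more than once.

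Genes were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM scaling, robust quasi-likelihood F test, 2-sided, Benjamini-Hochberg threshold 0.05). The SE of a log2 fold change is its size divided by the square root of F. The 7 genotype comparisons were fitted within each population over all its libraries; the 3 population comparisons, averaged over the genotypes both populations share, and the 4 tests of a difference of differences were fitted over all 24 libraries. CPM in genotype comparisons, and of Jak2 and Malat1 throughout, uses TMM factors of that population, and elsewhere factors over all 24 libraries. Xist and Y-linked levels are CPM without TMM scaling. Jak2 was also compared by an exact 2-sided permutation test of log2 CPM. Principal components used log2 CPM (prior count 2) of 500 genes.

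The comparisons, tests, alternatives, rule for named genes and 24 gene lists were chosen before the data were examined. The lists cover iron uptake, storage and export; heme synthesis; iron-sulfur clusters; globin; erythroid; megakaryocyte and platelet; stem cell; JAK-STAT target; interferon response; cell cycle; glycolysis and hypoxia; nuclear oxidative phosphorylation; cholesterol synthesis; unfolded protein and integrated stress response; immediate-early; NF-kB; p53 target; neutrophil and monocyte; lymphoid; mast, basophil and eosinophil; stroma and endothelium; histone; Jak2 neighbour and sex-linked genes. They were written from general knowledge and not taken from these samples, and a few genes stand in more than one list. Each list was tested with camera of limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. Each list's members were also counted with p-values adjusted over the list alone.

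The named genes of a genotype comparison are Jak2; the 10 higher and 10 lower genes of largest change with an adjusted p under 0.05, no overlap between the groups and a mean of at least 10 CPM in the higher group, without predicted genes, pseudogenes and sex-linked genes; list members with an adjusted p under 0.05, up to 5 per list; and, where fewer than 10 genes passed, the 5 of smallest p. For populations they are up to 5 members per direction of the stem cell, megakaryocyte and erythroid lists and the 10 largest changes each way, and for differences of differences the 5 largest each way. The text gives the main ones.

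The pipeline was tested on simulated data made from these counts. Genes changed 2-, 4- and 8-fold were recovered in 7.46%, 73.1% and 90.9% of cases for VF against KI in LTHSC, 1.49%, 22.4% and 72.7% in preMegE, 5.97%, 61.2% and 92.4% for E12 against KI in MkP, 52.2%, 95.5% and 100% between MkP and LTHSC, and 0%, 28.4% and 71.2% for a difference of differences. Between 2 and 10 unchanged genes were called per test, of 12762 to 14453. A shifted megakaryocyte list was found in all 5 tests. The simulated genes varied independently of each other, and no library was made to stand apart. These tests therefore do not show how list calls or false calls behave with correlated genes or with such libraries.

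Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, counts thinned to the smallest total, fits over all 24 libraries, over the 2 groups or over the 2 populations compared, the replicate number as a block, and leaving out each library in turn. After the data were seen, fits without the 4 libraries whose TMM factor was under 0.8, without genes on X and Y, with each library's gene-length trend removed, and with the Xist level as a covariate in MkP were added. Correlations of deviations between libraries of the same replicate number were not all above 0.1 in any set of 3 pairs. They were 0.256, 0.0542 and 0.217 for preMegE KI and VF and 0.11, 0.0643 and 0.087 for VF in LTHSC and MkP. Pairs of other numbers were not computed, so this does not show that the libraries are unpaired. The labels do not say whether a number marks the same mouse, so blocks appear as alternatives. The VF 2 libraries of LTHSC, preMegE and MkP held 533, 309 and 598 CPM of Xist beside Y-linked reads. The other VF libraries held at most 4.72 CPM of Xist. Libraries of VF with the same number may thus come from the same animals, and the fits between populations do not take this into account. No library was left out of the reported fits. Allele-specific reads of Jak2 were not analysed here, and 1 named gene and 1 test of the globin genes are not reported here.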

Results

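RNA was sequenced from 3 sorted bone marrow populations of C57BL/6N mice. LTHSC are long-term haematopoietic stem cells, preMegE are progenitors that can still form megakaryocytes and erythroid cells, and MkP are progenitors committed to megakaryocytes, the cells that shed platelets. The labels give 3 genotypes: KI, a Scl-Cre line with a mouse Jak2 knock-in, E12, a Scl-Cre line with a Jak2 exon 12 label, and VF, a Vav1-Cre line labelled with the valine-to-phenylalanine Jak2 mutation. Jak2 codes for a kinase that carries signals of blood cytokine receptors. The series describes JAK2-WT and mutant strains, but the sample labels do not say which group is unmutated, so KI served as the common reference and was not taken to be wild type. The Cre driver changed together with the VF genotype, so neither VF comparison separates the mutation from the driver. The 24 libraries formed 8 groups of 3, and no preMegE group of the E12 line was analysed here. The labels do not say whether replicates came from separate animals, so they may be technical, and the p-values measure the spread between these samples.

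Total counts per library ranged from 10357877 to 29691635, with 13245 to 16015 genes detected. In LTHSC the KI libraries held 12800097 to 16717145 counts, the E12 libraries 24076890 to 29415489 and the VF libraries 21630748 to 22271241. In preMegE the range was 14642836 to 28125309 for KI and 20799679 to 24952650 for VF. In MkP it was 10357877 to 29691635 for KI, 20751902 to 28601574 for E12 and 20354022 to 23023520 for VF. Levels are given as CPM of the TMM-scaled library, with SD and n = 3 unless another n is stated. Only Xist and Y-linked levels are CPM without TMM scaling.

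The first principal component of the 500 most variable genes held 54.1% of the variance and the second 15.3%. They separated the populations, except that LTHSC E12 replicate 4 lay at 10.9 on the first component while the other LTHSC libraries lay between -62.5 and -49.4. A TMM scaling factor under 0.8 within the population was found in 4 libraries: LTHSC E12 4 (0.754), preMegE KI 1 (0.589), MkP KI 5 (0.585) and MkP KI 6 (0.530). Each comparison was also fitted without these 4 libraries, an alternative chosen after seeing the data. In that fit MkP KI was left with 1 library, which was assumed to vary like the others.

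**Figure D1:**
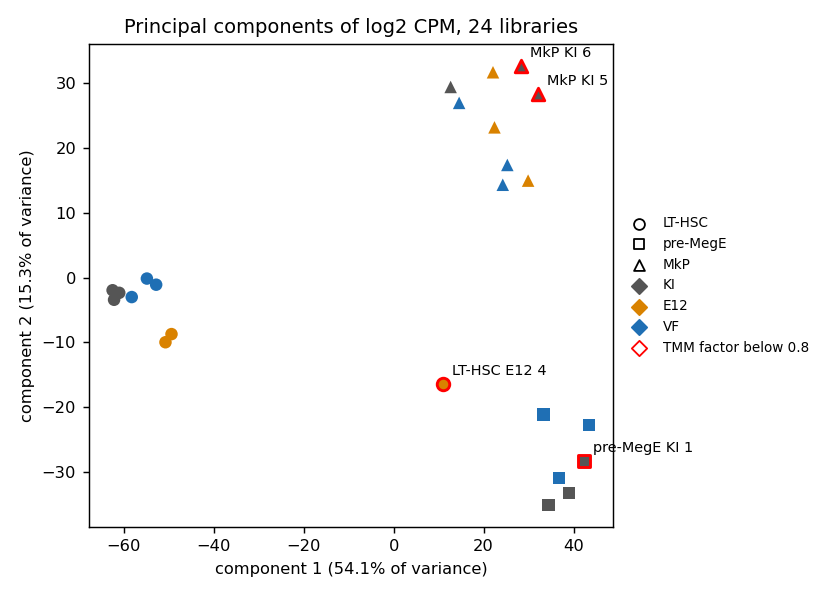
Scores of the 24 libraries on the first 2 principal components of log2 CPM of the 500 most variable genes, with the percent of variance on each axis, colour for genotype, marker for population and a red outline for a TMM factor under 0.8. LTHSC E12 4 lies at 10.9 on the first component, away from the other LTHSC libraries.

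Jak2 (Entrez 16452, chromosome 19, 29251803 to 29313095 in GRCm38) is the targeted gene, and its level was compared first as a look at the labels. In LTHSC it averaged 65.0 ± 15.2 CPM in KI, 48.2 ± 22.7 in E12 and 109 ± 10.2 in VF. In preMegE it averaged 29.0 ± 2.63 in KI and 46.5 ± 9.05 in VF, and in MkP 49.7 ± 15.0 in KI, 52.1 ± 5.47 in E12 and 70.7 ± 9.21 in VF. All 3 VF libraries lay above all 3 KI libraries in LTHSC (log2 0.74, SE 0.36, adjusted p = 0.662, exact permutation p = 0.1) and in preMegE (log2 0.68, SE 0.31, adjusted p = 0.642, exact permutation p = 0.1). In MkP the exact permutation p was 0.2 (log2 0.51, SE 0.26, adjusted p = 0.232). VF also lay above E12 in LTHSC (log2 1.17, SE 0.37, adjusted p = 0.44, exact permutation p = 0.1) and in MkP (log2 0.44, SE 0.26, adjusted p = 1, exact permutation p = 0.1). E12 and KI overlapped in LTHSC (log2 -0.43, SE 0.36, adjusted p = 0.582, exact permutation p = 0.4) and in MkP (log2 0.07, SE 0.26, adjusted p = 0.879, exact permutation p = 0.8). These permutation tests were 2-sided, 0.1 is the smallest p that 3 against 3 libraries allow, and no Jak2 difference passed the adjusted threshold. The scaling mattered where KI holds libraries of low TMM factor. Without TMM the difference of mean log2 Jak2 CPM was 1.20 for VF and 0.79 for E12 against KI in MkP (0.54 and 0.10 with it) and 0.93 for VF against KI in preMegE (0.65 with it). Counts per gene do not show which Jak2 allele was read, so the labels were not tested beyond this level.

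The comparison of VF with KI LTHSC asks which genes differ in stem cells of the VF line. Immediate-early genes, the quickly induced regulators of stress and growth signals, were lower in VF. Egr1, a transcription factor of this class (Entrez 13653, chromosome 18, 34861207 to 34864956), averaged 56 ± 15.2 CPM in VF and 2320 ± 498 in KI (log2 -5.37, SE 0.54, adjusted p = 0.00816). Junb, a subunit of the AP-1 factor, averaged 73.1 ± 11.2 against 686 ± 302 (log2 -3.23, SE 0.34, adjusted p = 0.00816). Dusp1, a phosphatase of MAP kinases, averaged 83.7 ± 15.1 against 1420 ± 522 (log2 -4.08, SE 0.61, adjusted p = 0.0485). Zfp36 (log2 -3.26), Klf2 (log2 -5.58) and Ier5 (log2 -2.37) also fell. Of the 27 measured members of the immediate-early list 6 fell and 0 rose over all genes, and 17 fell and 1 rose adjusted over the list alone. The list's median was log2 -2.78 (camera, adjusted p = 3.15e-18; adjusted p = 0.186 with an estimated correlation). Malat1, a nuclear RNA, also separated these libraries, at 3564 to 4927 CPM in KI and 1455 to 2191 in VF, so a difference in handling or RNA quality between the groups was not excluded. Ppp1r15a, a regulatory subunit of the phosphatase that ends the integrated stress response, averaged 113 ± 19.3 against 974 ± 135 (log2 -3.10, SE 0.35, adjusted p = 0.0103).

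Genes of the platelet and red cell programmes were higher in VF LTHSC. Pf4, a platelet chemokine, averaged 132 ± 35.5 CPM against 22.0 ± 8.67 (log2 2.59, SE 0.38, adjusted p = 0.0483). Mfsd2b, a lipid exporter of red cells and platelets, averaged 77.1 ± 20 against 15.0 ± 6.39 (log2 2.37, SE 0.36, adjusted p = 0.0485), and Aqp1, the red cell water channel, 107 ± 12.6 against 21.7 ± 3.36 (log2 2.30, SE 0.30, adjusted p = 0.0304). Of 29 measured erythroid members 2 rose over all genes and 4 adjusted over the list alone (median log2 0.90, camera adjusted p = 2.38e-05; adjusted p = 0.054 with an estimated correlation). Of 41 megakaryocyte and platelet members 1 rose over all genes and 7 adjusted over the list alone (median 0.58, camera adjusted p = 0.000241; adjusted p = 0.26 with an estimated correlation). None of the 6 globin genes passed over all genes and 6 rose adjusted over the list alone (median 1.54, camera adjusted p = 1.61e-07; adjusted p = 0.186 with an estimated correlation). Echdc2, an enoyl-CoA hydratase domain gene (Entrez 52430, chromosome 4, 108165436 to 108179308), was at 4.92 ± 1.08 CPM in VF and 262 ± 38.9 in KI (log2 -5.73, SE 0.30, adjusted p = 1.91e-05). The secreted glycoprotein gene Lrg1 (2.04 ± 0.56 against 14.8 ± 4.87 CPM) and the myosin light chain gene Myl10 (73.0 ± 23.2 against 397 ± 94.1 CPM), both with adjusted p = 0.0304, fell by 2.85 and 2.44 on the log2 scale.

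In the remaining lists of VF against KI LTHSC, with all libraries, no member of the cell cycle or interferon list passed over all genes. Adjusted over the list alone, 6 of 50 cell cycle members rose (median log2 0.66, camera adjusted p = 3.13e-15; adjusted p = 0.186 with an estimated correlation), and 3 of 52 interferon response members rose (median 0.40, camera adjusted p = 3.39e-07; adjusted p = 0.186 with an estimated correlation). Cholesterol synthesis genes had a median of -0.52, with 0 of 24 passing over all genes or over the list alone (camera adjusted p = 5.1e-06; adjusted p = 0.192 with an estimated correlation). Neutrophil and monocyte genes had a median of -1.56, with 0 of 27 passing over all genes and 7 falling adjusted over the list alone (camera adjusted p = 2.38e-05; adjusted p = 0.449 with an estimated correlation). Stroma and endothelium markers had a median of 1.00, with 0 of 11 passing over all genes and 2 rising adjusted over the list alone (camera adjusted p = 0.00593; adjusted p = 0.186 with an estimated correlation). Because the series title names iron, the iron lists were of interest. Over all genes or over the list alone 0 of 30 genes of iron uptake, storage and export (median -0.08, camera adjusted p = 0.771), 0 of 14 of heme synthesis (median 0.02 but mean -0.11, adjusted p = 0.683) and 0 of 24 of iron-sulfur cluster assembly (median -0.13, adjusted p = 0.779) passed. The JAK-STAT target list had 1 lower member of 25 (Junb, also in the immediate-early list) and 2 lower adjusted over the list alone (camera adjusted p = 0.771). The unfolded protein and stress list had 1 lower member of 29 (Ppp1r15a), and 1 higher and 1 lower adjusted over the list alone, with a median of 0.08, a mean of -0.32 and a camera adjusted p of 0.522. By camera the adjusted p was 0.683 for stem cell genes, 0.0542 for NF-kB genes, 0.823 for p53 targets, 0.49 for glycolysis and hypoxia, 0.347 for nuclear oxidative phosphorylation genes and 0.157 for histone genes. It was 0.77 for lymphoid, 0.771 for mast, basophil and eosinophil, 0.683 for Jak2 neighbour and 0.586 for sex-linked genes. With all libraries none of these 10 lists had a member that passed over all genes. Adjusted over the list alone 4 NF-kB genes and 1 p53 target fell and no member of the other 8 passed.

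By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 genes rose and 10 fell in VF LTHSC among 14161 tested (1148 at an unadjusted p under 0.05). The 3 VF and 3 KI libraries did not overlap for any of these 13 genes, which chance gives for 10% of genes. DESeq2 called 287 genes and limma voom 1232, and edgeR 705 with the replicate number as a block and 931 with only the 2 groups compared. The count fell to 4, 7 and 3 without KI 1, 2 and 3, and to 1, the gene Echdc2, without VF 1, 2 or 3. Mfsd2b and Dusp1 no longer passed with RLE scaling (adjusted p = 0.0515 for both).

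LTHSC E12 4, which is not part of this comparison, took part in the shared variance estimate. Without it 149 genes rose and 144 fell, among them all 13. The genes named here from that fit were chosen after seeing the data. The platelet adhesion gene Vwf averaged 235 ± 59.5 CPM in VF and 41.0 ± 3.79 in KI (log2 2.52, SE 0.19, adjusted p = 0.00107). Gata1, the transcription factor of both lineages, averaged 93.2 ± 12.6 against 33.8 ± 1.84 (log2 1.46, SE 0.15, adjusted p = 0.00456). Itga2b, the platelet integrin CD41, averaged 270 ± 74.7 against 91.0 ± 20.2 (log2 1.57, SE 0.24, adjusted p = 0.0197). Socs2, a JAK-STAT target, averaged 248 ± 21.7 against 131 ± 23.3 (log2 0.92, SE 0.17, adjusted p = 0.0311). Of 25 JAK-STAT targets it alone rose over all genes, while Junb, Myc (log2 -0.76) and Mcl1 (log2 -1.19) fell, with 3 higher and 3 lower over the list alone (camera adjusted p = 0.815). In this fit 8 of 42 megakaryocyte members rose over all genes (12 higher and 2 lower adjusted over the list alone) and 13 of 27 immediate-early members fell (17 lower and 2 higher adjusted over the list alone). For cell cycle genes, including the spindle motor Kif11 (log2 1.39, SE 0.17, adjusted p = 0.0109), 11 of 50 rose (43 adjusted over the list alone). With an estimated correlation the adjusted p was 0.429, 0.371 and 0.344 for these 3 lists. Of 53 interferon members 5 rose over all genes and 21 over the list alone (adjusted p = 0.371 with an estimated correlation). Of 34 stem cell members 5 rose over all genes, and 9 rose and 3 fell over the list alone (camera adjusted p = 0.579). Over all genes 2 NF-kB genes and 1 p53 target also fell, and 1 glycolysis and 1 oxidative phosphorylation gene rose.

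**Figure D2:**
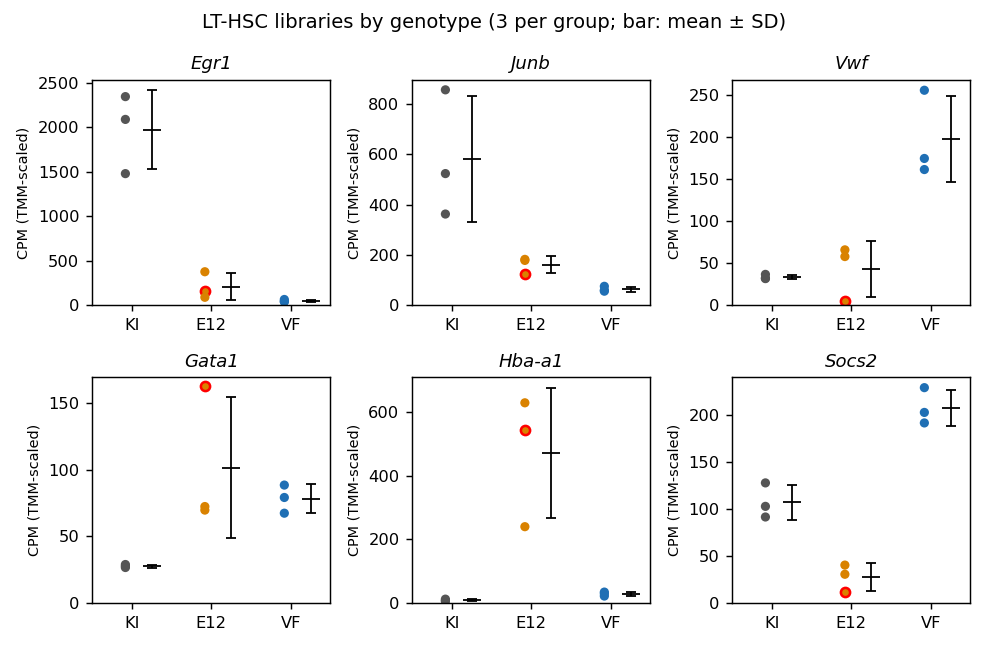
CPM (TMM over all 24 libraries) of Egr1, Junb, Vwf, Gata1, Hba-a1 and Socs2 in the 9 LTHSC libraries, with genotype on the horizontal axis, CPM from 0 on the vertical axis, points for libraries and bars for the mean and SD of 3 libraries. Vwf and Gata1 were chosen after seeing the data, and the 3 VF libraries lie below the 3 KI libraries for Egr1 and Junb.

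The comparison of E12 with KI LTHSC asks the same of the exon 12 line. Globin genes, which code for the chains of haemoglobin, were higher in E12 stem cells. Hba-a1 (Entrez 15122, chromosome 11, 32283672 to 32284486) averaged 550 ± 237 CPM in E12 and 9.77 ± 3.50 in KI (log2 5.82, SE 0.46, adjusted p = 0.000776). Hbb-bs averaged 121 ± 51.9 against 10.9 ± 4.57 (log2 3.48, SE 0.44, adjusted p = 0.0304). Hba-a2 and Hbb-b1 share reads with them, so the 4 called globin genes stand for 1 alpha and 1 beta locus. Of 6 measured globin genes 4 rose over all genes and 6 adjusted over the list alone (median 3.48, camera adjusted p = 5.12e-14; adjusted p = 0.187 with an estimated correlation). No erythroid member passed over all genes, while 16 of 29 rose adjusted over the list alone (median 1.88, camera adjusted p = 2.57e-11), a list call that held with an estimated correlation (adjusted p = 0.00528). Gpc3, a cell surface proteoglycan gene on chromosome X, rose (10.9 ± 6.57 against 0.31 ± 0.16 CPM, log2 5.07, SE 0.67, adjusted p = 0.0405). Myl10 fell (74.2 ± 23.0 against 397 ± 94.1 CPM, log2 -2.42, SE 0.33, adjusted p = 0.0495).

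No cell cycle or immediate-early member passed over all genes in E12 against KI LTHSC. Adjusted over the list alone, 33 of 50 cell cycle members rose (median 0.88, camera adjusted p = 3.19e-14, adjusted p = 0.324 with an estimated correlation). In the same way 15 of 27 immediate-early members fell while 1 rose (median -1.87, camera adjusted p = 2.7e-10, adjusted p = 0.324 with an estimated correlation). Malat1 was at 1938 to 3315 CPM in E12 and 3564 to 4927 in KI, so a difference in handling or RNA quality was not excluded here either. Neutrophil and monocyte genes (median 0.89, 10 of 27 higher adjusted over the list alone, camera adjusted p = 0.00179), mast, basophil and eosinophil genes (median 4.37, 7 of 14, adjusted p = 0.000443) and stem cell genes (median -0.40, 1 higher and 1 lower of 34, adjusted p = 0.00397) moved with 1 library, and none of their members passed over all genes. LTHSC E12 4 held 16070 CPM of Mpo, the neutrophil myeloperoxidase. Without it the 3 medians were -0.35 (adjusted p = 0.567), 1.47 (adjusted p = 0.25) and 0.04 (adjusted p = 0.789). With all libraries the estimated-correlation adjusted p values of these lists were 0.469, 0.324 and 0.583. Iron handling genes had a median of 0.21 and a mean of -0.14, with 0 of 30 passing over all genes or over the list alone (camera adjusted p = 0.645).

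By edgeR 5 genes rose and 1 fell in E12 LTHSC among 14161 tested (1957 at an unadjusted p under 0.05), each without overlap between the groups, and with RLE scaling 5 rose and 0 fell because Myl10 no longer passed (adjusted p = 0.0513). DESeq2 called 467 genes and limma voom 8; the count was 379 without E12 2, 18 without E12 4, and 2 without E12 11 or without any of the 3 KI libraries. The 18 genes without E12 4 held all 6, and from that fit (E12 n = 2), chosen after seeing the data, Gata1 averaged 84.0 ± 4.04 CPM against 33.8 ± 1.84 (log2 1.31, SE 0.16, adjusted p = 0.0252), and Socs2 42.0 ± 9.09 against 131 ± 23.3 (log2 -1.65, SE 0.20, adjusted p = 0.0252). In that fit all 6 globin genes rose, as did 2 of 29 erythroid members (11 adjusted over the list alone; adjusted p = 0.0126 with an estimated correlation).

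The comparison of VF with E12 LTHSC asks where these 2 lines differ. Socs2, a feedback inhibitor of JAK-STAT signalling (Entrez 216233, chromosome 10, 95383903 to 95417321), was higher in VF at 239 ± 20.6 CPM against 31.7 ± 16.4 (log2 2.92, SE 0.39, adjusted p = 0.0431). Hba-a1 was lower in VF at 32.6 ± 7.04 against 550 ± 237 (log2 -4.08, SE 0.42, adjusted p = 0.00701), as was Hba-a2, of the same locus. Echdc2 was at 4.92 ± 1.08 CPM in VF and 388 ± 70.1 in E12 (log2 -6.30, SE 0.31, adjusted p = 9.3e-06). Lrg1 was at 2.04 ± 0.56 and 19.9 ± 1.66 (log2 -3.28, SE 0.39, adjusted p = 0.0166). Of 6 globin genes 2 fell over all genes and 6 adjusted over the list alone (median -1.95, camera adjusted p = 1.68e-09; adjusted p = 0.309 with an estimated correlation). Of 25 JAK-STAT targets 1 rose over all genes, and 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.711). Neutrophil and monocyte genes had 0 of 27 members passing over all genes and 22 lower adjusted over the list alone (median -2.37, camera adjusted p = 6.12e-13; adjusted p = 0.309 with an estimated correlation); without LTHSC E12 4 the median was -1.59 with 14 lower adjusted over the list alone.

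By edgeR 1 gene rose and 4 fell in VF against E12 LTHSC (1562 of 14161 at an unadjusted p under 0.05), none with overlapping groups, against 185 by DESeq2 and 17 by limma voom. The count was 306 without E12 2, 13 without E12 4, 4 without E12 11 and 1, the gene Echdc2, without VF 1, 2 or 3. Among the 13 genes called without E12 4, which held all 5, Vwf averaged 235 ± 59.5 CPM in VF and 73.4 ± 8.26 in E12 (n = 2; log2 1.68, SE 0.21, adjusted p = 0.0314), a gene chosen after seeing the data.

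The comparison of VF with KI preMegE asks the same question at the step where the megakaryocyte and erythroid paths part. Echdc2 averaged 0.42 ± 0.40 CPM in VF and 140 ± 37.0 in KI (log2 -8.37, SE 0.94, adjusted p = 0.0426). Fosb, an immediate-early AP-1 gene (Entrez 14282, chromosome 7, 19302696 to 19310118), averaged 1.47 ± 1.00 against 53.8 ± 21.7 (log2 -5.20, SE 0.59, adjusted p = 0.0426). Fos at 13.8 ± 7.71 against 355 ± 101 CPM (log2 -4.68, SE 0.57, adjusted p = 0.0506) and Egr1 at 17.8 ± 5.46 against 171 ± 56.2 (log2 -3.26, SE 0.43, adjusted p = 0.0749) did not pass, though no VF library reached a KI library for either. Of 24 immediate-early members 1 fell over all genes and 16 adjusted over the list alone (median -1.63, camera adjusted p = 2.08e-16; adjusted p = 0.166 with an estimated correlation). None of 22 lymphoid members passed over all genes and 13 fell adjusted over the list alone (median -1.80, camera adjusted p = 1.67e-11, and adjusted p = 0.227 with an estimated correlation). Whether the sorts differed in lymphoid cells was not tested. None of 27 neutrophil and monocyte members passed over all genes and 6 rose adjusted over the list alone (median 0.46, camera adjusted p = 0.0116; adjusted p = 0.793 with an estimated correlation). Erythroid genes (median -0.18, camera adjusted p = 0.0733), iron handling genes (median 0.18, adjusted p = 0.862) and heme synthesis genes (median -0.08, adjusted p = 0.844) were not called as lists with all libraries. In these, 0 of 29, 0 of 28 and 0 of 14 members passed over all genes, and 0, 1 and 0 adjusted over the list alone.

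The nuclear oxidative phosphorylation, histone and globin lists had medians of -1.70, -1.73 and -1.98 in preMegE VF against KI (camera adjusted p = 6.21e-06, 0.000239 and 0.0055; adjusted p = 0.673, 0.673 and 0.653 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. Without KI 1 these medians were 0.35 (adjusted p = 0.425), 0.16 (adjusted p = 0.895) and -0.26 (adjusted p = 0.232). In the same fit the erythroid list was lower (median -0.34, camera adjusted p = 0.00459, and adjusted p = 0.904 with an estimated correlation), with 0 of 29 members passing over all genes or over the list alone. By library the mean log2 CPM of the erythroid list was 5.879 in VF 1, 7.045 in VF 2 and 6.919 in VF 3. In KI 2 and KI 3 it was 6.852 and 7.172, so only VF 1 lay below both. Genes named from that fit (KI n = 2) were chosen after seeing the data. The neutrophil granule genes Elane, at 1290 ± 966 CPM against 76.4 ± 3.91 (log2 4.08, SE 0.56, adjusted p = 0.0023), and Mpo, at 8220 ± 1790 against 1560 ± 288 (log2 2.40, SE 0.40, adjusted p = 0.00822), rose in VF. Fos fell to 15.4 ± 8.42 from 386 ± 165 (log2 -4.65, SE 0.45, adjusted p = 2.39e-05). Erfe, the erythroid hormone that lowers hepcidin, fell to 2.81 ± 0.54 from 13.5 ± 4.80 (log2 -2.26, SE 0.46, adjusted p = 0.0472). It was the only 1 of 28 iron handling members to pass over all genes, with 1 higher and 1 lower over the list alone, and the list was not called (median -0.05, camera adjusted p = 0.895). Of the lists 8 of 24 immediate-early members fell (14 adjusted over the list alone, and 1 rose), 5 of 27 neutrophil and monocyte members rose (10 adjusted over the list alone) and 2 of 22 lymphoid members fell (9 adjusted over the list alone). Their adjusted p was 0.527, 0.904 and 0.709 with an estimated correlation. The mean log2 CPM of the neutrophil and monocyte list was 6.666 in VF 1, 4.095 in VF 2 and 5.267 in VF 3. In KI 2 and KI 3 it was 5.075 and 4.885, so VF 2 lay below both. The CPM sum of this list was higher in every VF library, at 9050 to 20490 against 3880 in KI 2 and 3385 in KI 3.

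By edgeR 0 genes rose and 2 fell in preMegE VF among 13238 tested (871 at an unadjusted p under 0.05), against 66 by DESeq2 and 70 by limma voom. With RLE scaling the count was 0. It was 31 without KI 1, 5 without KI 2, 1 without VF 2 and 0 without VF 1 or VF 3.

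In MkP the comparisons with KI ask how committed megakaryocyte progenitors of the VF and E12 lines differ from those of the KI line. Megakaryocyte and platelet genes had a positive median in both lines, with 0 of 43 members passing over all genes. Adjusted over the list alone 7 rose and 1 fell in VF (median 0.80, camera adjusted p = 1.45e-05; adjusted p = 0.601 with an estimated correlation), and 13 rose and 2 fell in E12 (median 0.89, camera adjusted p = 7.27e-06; adjusted p = 0.581 with an estimated correlation). Serpine2, a protease inhibitor gene of the megakaryocyte list, averaged 342 ± 48.3 CPM in VF and 44.8 ± 31.1 in KI (log2 2.93, SE 0.46, adjusted p = 0.0756). The actin-severing gelsolin gene Gsn averaged 53.3 ± 13 in E12 and 16.5 ± 1.33 in KI (log2 1.69, SE 0.26, adjusted p = 0.0615). Socs2 averaged 9.52 ± 2.80 in E12 against 39.6 ± 10.7 in KI (log2 -2.06, SE 0.33, adjusted p = 0.0615). None of these single genes passed, though in each the groups did not overlap. Globin genes had a median of 2.60 in E12 against KI, with 0 of 6 passing over all genes and 6 rising adjusted over the list alone (camera adjusted p = 0.000852; adjusted p = 0.581 with an estimated correlation). Iron handling genes had medians of 0.35 in VF (camera adjusted p = 0.45) and 0.30 in E12 (adjusted p = 0.357), and heme synthesis genes of 0.63 in VF (adjusted p = 0.194). In these, 0 of 28, 0 of 28 and 0 of 14 members passed over all genes, and 1, 0 and 0 adjusted over the list alone.

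Nuclear oxidative phosphorylation genes had a median of -3.01 in MkP VF and -3.12 in E12 against KI (camera adjusted p = 1.93e-10 and 1e-09; adjusted p = 0.601 and 0.581 with an estimated correlation), with 0 of 71 passing over all genes and 55 lower in each adjusted over the list alone, beside 1 higher in E12. Histone genes had medians of -3.23 and -3.26 (camera adjusted p = 1.45e-05 and 4.45e-05; adjusted p = 0.601 and 0.581 with an estimated correlation), with 0 of 19 passing over all genes and 18 and 15 lower adjusted over the list alone. These lists moved with MkP KI 5 and KI 6: without them the oxidative phosphorylation medians were 0.35 (camera adjusted p = 2.96e-09) and 0.27 (7.2e-07), and the histone medians 0.58 (0.00859) and 0.45 (0.00233), the opposite direction. With an estimated correlation these calls were lost too (adjusted p = 0.786 for both lists in VF and adjusted p = 0.605 in E12). In that fit, against the lone KI 4 and chosen after seeing the data, the platelet genes Serpine2 (log2 2.08, SE 0.21, adjusted p = 0.00184), Pf4 (log2 1.41, SE 0.26, adjusted p = 0.0443) and the tetraspanin gene Cd9 (log2 0.86, SE 0.15, adjusted p = 0.0401) rose in VF. Tfrc, the transferrin receptor that brings iron into cells, fell in VF to 65.6 ± 9.98 CPM from 149 (log2 -1.19). With all libraries Tfrc did not pass (log2 -0.34, SE 0.41, adjusted p = 0.601), as KI 5 and KI 6, at 38.1 and 46.8 CPM scaled over all 24 libraries, lay below all VF libraries. KI 4 held 2719 CPM of Xist and 0.168 of Y-linked genes without TMM scaling. VF 1 and VF 3 held 1.96 and 1.33 of Xist and 143.5 and 152.9 of Y-linked genes. Sex was thus not separated from genotype in the fit against KI 4. Of 44 megakaryocyte members 3 rose in VF and 5 in E12 (16 and 20 adjusted over the list alone; adjusted p = 0.786 and 0.605 with an estimated correlation).

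**Figure D3:**
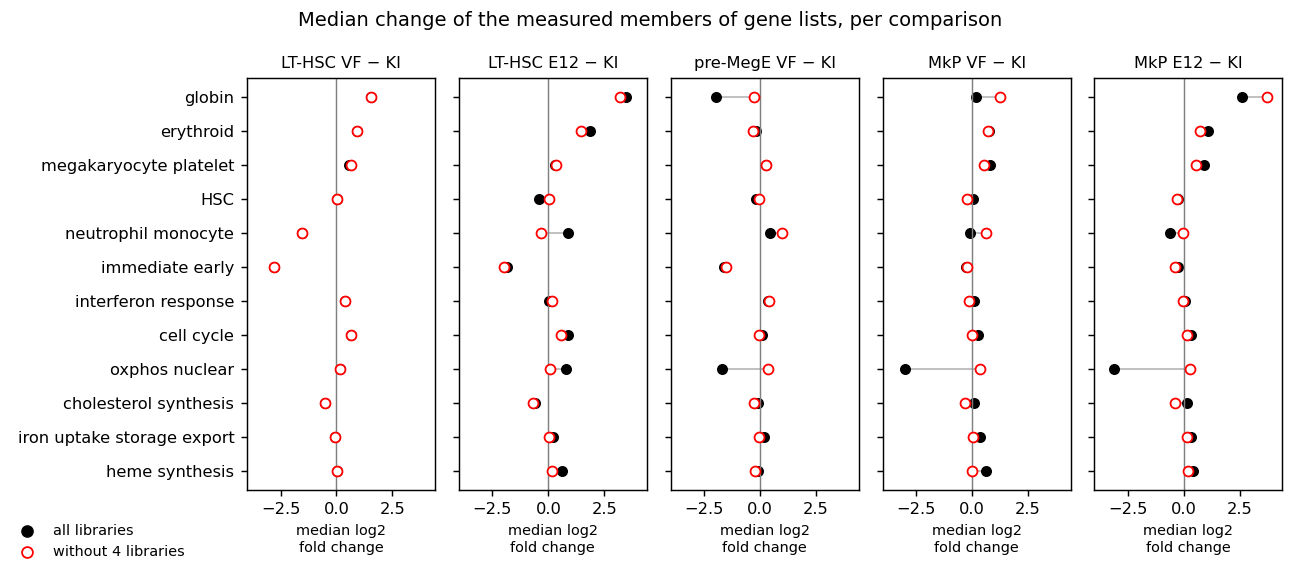
Median log2 fold change (horizontal axis) of the members of 12 gene lists in 5 genotype comparisons, with black points for all libraries and open red points without the 4 libraries of TMM factor under 0.8. The oxidative phosphorylation list in MkP VF against KI moves from -3.01 to 0.35.

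Between the VF and E12 lines, VF MkP held more Socs2 than E12 MkP at 46.1 ± 10.9 against 9.52 ± 2.80 CPM (log2 2.28, SE 0.33, adjusted p = 0.558). It held less of the clotting inhibitor gene Tfpi at 20 ± 2.57 against 51.2 ± 3.86 (log2 -1.35, SE 0.23, adjusted p = 0.741). Neither difference passed. Globin genes had a median of -2.44, with 0 of 6 passing over all genes and 6 lower adjusted over the list alone (camera adjusted p = 3.81e-15; adjusted p = 0.301 with an estimated correlation). Neutrophil and monocyte genes had a median of 0.73, with 0 of 26 passing over all genes or over the list alone (camera adjusted p = 7.52e-07; adjusted p = 0.679 with an estimated correlation). Iron handling (median 0.06, camera adjusted p = 0.944, 0 of 28 over all genes or the list alone) and megakaryocyte genes (median -0.05, adjusted p = 0.63, 0 of 43 over all genes or the list alone) did not move as lists. E12 4 and E12 5 held 2004 and 2061 CPM of Xist without TMM scaling, and VF 1 and VF 3 held 1.96 and 1.33. E12 2 and VF 2 held 869 and 598 beside Y-linked reads. Sex was not balanced between these groups, so it was not separated from genotype. Neither of them holds a library with a TMM factor under 0.8, but MkP KI 5 and 6 took part in the shared variance. Without them, and chosen after seeing the data, Socs2 (log2 2.28, SE 0.25, adjusted p = 0.00588) and the neutrophil progenitor gene Ms4a3 (132 ± 42.2 against 45.9 ± 6.89 CPM, log2 1.52, SE 0.22, adjusted p = 0.0353) rose in VF. Tfrc fell to 65.6 ± 9.98 from 168 ± 9.05 CPM (log2 -1.36, SE 0.13, adjusted p = 0.00204), while with all libraries its log2 value was -1.36 with an SE of 0.41 and an adjusted p of 1. The oestrogen receptor gene Esr1 fell to 14.5 ± 2.14 from 56.4 ± 6.37 CPM (log2 -1.96, SE 0.18, adjusted p = 0.00153). Echdc2 fell to 1.41 ± 1.01 from 205 ± 2.52 (log2 -7.16, SE 0.35, adjusted p = 2.41e-05).

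By edgeR 0 of 13443 genes passed in VF against KI MkP (3611 at an unadjusted p under 0.05, smallest adjusted p = 0.0756), against 2570 by DESeq2 and 4111 by limma voom. In E12 against KI 0 passed (3900 at an unadjusted p under 0.05, smallest adjusted p = 0.0615), against 2847 by DESeq2 and 4203 by limma voom, and in VF against E12 0 passed (168, smallest adjusted p = 0.558), against 11 and 39. Without MkP KI 4 the counts against KI were 6738 for VF and 6862 for E12, and without KI 5 and KI 6 together they were 60 and 99, with 12 for VF against E12. MkP KI 4, E12 4 and E12 5 were high in Xist with under 0.3 CPM of Y-linked genes, so sex was not balanced between the MkP groups.

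**Figure D4:**
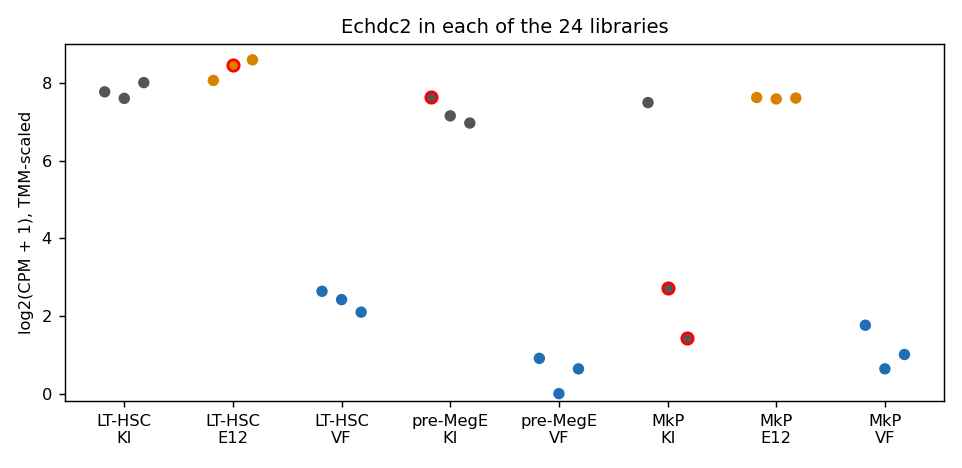
Echdc2 level as log2 of CPM (TMM over all 24 libraries) plus 1 on the vertical axis, in each of the 24 libraries, with colour for genotype and a red outline for a TMM factor under 0.8. The 9 VF libraries lie at 0 to 5.21 CPM, MkP KI 5 and KI 6 at 5.53 and 1.70, and the other 13 at 124 to 385.

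The comparisons between populations ask what marks each step of the sorted hierarchy, with CPM scaled over all 24 libraries. From LTHSC to MkP (n = 9 each) platelet genes rose, among them Itga2b from 166 ± 90.5 to 1280 ± 473 CPM (log2 3.00, SE 0.23, adjusted p = 2.63e-09). Treml1, a platelet granule receptor, rose from 7.91 ± 4.09 to 115 ± 42.6 (log2 3.97, SE 0.25, adjusted p = 1.77e-10), and Slc35d3, a nucleotide sugar transporter of platelet dense granules, from 4.66 ± 2.61 to 117 ± 44.2 (log2 4.73, SE 0.24, adjusted p = 2.68e-11). Stem cell genes fell, among them Procr, the stem cell marker EPCR, from 65.1 ± 12.7 to 0.86 ± 1.30 (log2 -6.65, SE 0.56, adjusted p = 1.37e-08). The transcription factor Hlf fell from 190 ± 85.3 to 22.3 ± 4.55 (log2 -3.08, SE 0.27, adjusted p = 2.57e-08). Of 43 megakaryocyte members 30 rose and 1 fell (32 and 1 adjusted over the list alone, camera adjusted p = 3.09e-16). Of 50 cell cycle members 45 rose (47 adjusted over the list alone, adjusted p = 1.28e-19). Of 25 NF-kB members 2 rose and 12 fell (3 and 14 adjusted over the list alone, camera adjusted p = 0.00125). Each of these 3 lists had an adjusted p of 0.043 with an estimated correlation. Of 34 stem cell members 1 rose and 19 fell (1 and 19 adjusted over the list alone, camera adjusted p = 1.64e-06; adjusted p = 0.264 with an estimated correlation). Of 53 interferon members 34 fell (36 adjusted over the list alone, adjusted p = 1.71e-08; adjusted p = 0.0665 with an estimated correlation). Iron handling genes moved both ways, 3 of 30 higher and 4 lower over all genes and over the list alone (camera adjusted p = 0.664). LTHSC E12 4 stood apart in the stem cell list, with 27 of 33 members below every other LTHSC library.

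From LTHSC to preMegE (n = 6 each) red cell genes rose. Klf1, the erythroid transcription factor, went from 11.8 ± 6.09 to 712 ± 263 CPM (log2 6.07, SE 0.42, adjusted p = 8.83e-09). The blood group genes rose too, Ermap from 0.91 ± 0.63 to 348 ± 119 (log2 8.57, SE 0.75, adjusted p = 9.6e-08) and Kel from 0.68 ± 0.57 to 88.1 ± 36.5 (log2 7.47, SE 0.67, adjusted p = 1.19e-07). Ly6a, the Sca-1 antigen used to sort stem cells, fell from 194 ± 40.1 to 7.43 ± 4.32 (log2 -4.73, SE 0.43, adjusted p = 1.19e-07). Of 29 erythroid members 25 rose (26 adjusted over the list alone, camera adjusted p = 7.97e-22; adjusted p = 0.00262 with an estimated correlation). Of 14 heme synthesis members 11 rose (12 adjusted over the list alone, camera adjusted p = 2.16e-06; adjusted p = 0.0684 with an estimated correlation). Of 24 iron-sulfur cluster members 16 rose over all genes and over the list alone (camera adjusted p = 6.13e-06; adjusted p = 0.0943 with an estimated correlation). Of 30 iron handling members 10 rose and 3 fell (10 and 4 adjusted over the list alone, camera adjusted p = 0.112), with Tfrc at log2 3.16. Of 34 stem cell members 28 fell over all genes and over the list alone (camera adjusted p = 1.04e-14; adjusted p = 0.0727 with an estimated correlation). Of 23 lymphoid members 19 rose and 1 fell over all genes and over the list alone (median 6.80, camera adjusted p = 2.26e-09, and adjusted p = 0.0684 with an estimated correlation), among them the pre-B cell gene Igll1 at 162 ± 184 CPM in preMegE. The CPM sum of this list was uneven, at 1141 to 5930 in preMegE KI and 870 to 1471 in preMegE VF. RNA of lymphoid cells in the sort was not tested as its source.

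From preMegE to MkP (n = 6 each) the erythroid programme fell and the platelet programme rose. Klf1 averaged 80.4 ± 19.9 CPM in MkP and 712 ± 263 in preMegE (log2 -3.14, SE 0.36, adjusted p = 2.42e-05), and the Rhesus antigen gene Rhd 7.54 ± 6.51 and 338 ± 174 (log2 -5.78, SE 0.65, adjusted p = 1.99e-05). Treml1 averaged 97.6 ± 42.2 and 25.1 ± 5.87 (log2 1.92, SE 0.27, adjusted p = 0.000163) and Cavin2 280 ± 55.3 and 55.4 ± 19.0 (log2 2.34, SE 0.35, adjusted p = 0.000247). Of 29 erythroid members 20 fell (23 adjusted over the list alone, camera adjusted p = 5.01e-23). Of 43 megakaryocyte members 26 rose (36 adjusted over the list alone, adjusted p = 2.17e-25). Of 14 heme synthesis members 10 fell (11 adjusted over the list alone, camera adjusted p = 2.17e-10). Of 30 iron handling members 8 fell (10 adjusted over the list alone, adjusted p = 0.000531), with Tfrc at log2 -1.69. Of 23 lymphoid members 17 fell (19 adjusted over the list alone, camera adjusted p = 1.88e-21). These 5 lists had an adjusted p of 0.00212, 0.00339, 0.0104, 0.0104 and 0.00339, in this order, with an estimated correlation. They and the 4 calls of the steps from LTHSC, with the erythroid list of E12 against KI LTHSC, were the 10 of 138 list calls that held with one. All 6 globin genes fell over all genes and over the list alone (median -2.77, camera adjusted p = 3.97e-09; adjusted p = 0.0739 with an estimated correlation).

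By edgeR 2549 genes rose and 2649 fell from LTHSC to MkP among 14975 tested, 3178 rose and 2911 fell from LTHSC to preMegE, and 490 rose and 638 fell from preMegE to MkP. In the last the count was 1840 without preMegE KI 1, 1912 without MkP KI 4, 739 without preMegE VF 2, 726 without preMegE VF 3 and 695 without MkP VF 1. DESeq2 called 1790 genes and limma voom 3851. With the replicate number as a block the count from LTHSC to MkP was 2279. The VF 2 libraries of all 3 populations held 309 to 598 CPM of Xist beside Y-linked reads, and the other VF libraries at most 4.72 CPM of Xist. VF libraries of the same number may thus share animals, and the count without the block treats them as independent.

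Tests of the difference of differences ask whether a genotype effect differs between populations. The VF effect on Egr1 was higher in MkP than in LTHSC by log2 4.34 (SE 0.62, adjusted p = 0.00518) and that on Ppp1r15a by 3.50 (SE 0.51, adjusted p = 0.00518). Egr1 was at 48.7 CPM in VF and 1970 in KI in LTHSC, and at 31.1 and 61.9 in MkP. Of 27 immediate-early members 1 rose over all genes in this test and 19 rose and 1 fell adjusted over the list alone (median 2.26, camera adjusted p = 7.9e-13; adjusted p = 0.15 with an estimated correlation). The E12 effect on Ppp1r15a was higher in MkP than in LTHSC by 3.06 (SE 0.51, adjusted p = 0.0486). That on the mast cell receptor gene Fcer1a was lower by 7.09 on the log2 scale (value -7.09, SE 1.27, adjusted p = 0.0486). By edgeR the VF effect differed between MkP and LTHSC for 2 genes, both higher (2152 at an unadjusted p under 0.05), and the E12 effect for 5, of which 1 was higher and 4 lower (3644). The VF effect differed for 0 genes between MkP and preMegE (699 at an unadjusted p under 0.05, DESeq2 21, limma voom 2234) and for 0 between preMegE and LTHSC (663, DESeq2 11, limma voom 7).

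Without the 4 libraries of low TMM factor the VF test between MkP and LTHSC and the E12 test called 0 genes, and the VF test between preMegE and LTHSC called 33. Without MkP KI 4 the counts were 2615 and 4532 for VF and E12 between MkP and LTHSC and 78 for VF between MkP and preMegE. The VF count between MkP and LTHSC was 4 without MkP VF 3. The E12 count was 1552 without LTHSC E12 2, 759 without E12 11, 1 without MkP E12 4 and 0 without any one other library among LTHSC KI 1, 2 and 3, LTHSC E12 4, MkP KI 5 and 6, and MkP E12 2 and 5. The VF count between MkP and preMegE was 1 without MkP VF 3. RLE scaling moved the median of all genes in the E12 test by -0.108.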

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

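The tests of an effect that differs between populations and of other splits of the libraries were planned, as was the test of gene length for the 4 libraries that stood apart and for Echdc2; the tests of depth, of RNA from other cells, of a wrong label, of a linked region, and all those of the globin genes were chosen after the result was seen.

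A genotype effect that differed between populations singled out 7 values, with CPM scaled over all 24 libraries. The VF effect on Egr1 was higher in MkP than in LTHSC by log2 4.34 (SE 0.62, adjusted p = 0.00518), with mean CPM of 31.1 in VF and 61.9 in KI in MkP against 48.7 and 1970 in LTHSC. That on Ppp1r15a was higher by 3.50 (SE 0.51, adjusted p = 0.00518; 72.6 and 53.8 against 98.5 and 825), and the E12 effect on it by 3.06 (SE 0.51, adjusted p = 0.0486; 95.9 and 53.8 against 177 and 825). The E12 effect was lower in MkP than in LTHSC for Fcer1a (log2 -7.09, SE 1.27, adjusted p = 0.0486; 36.6 and 240 against 23.9 and 1.13), for the filament gene Vim (-2.61, SE 0.48, adjusted p = 0.0486; 37.3 and 105 against 185 and 84.7) and for Tespa1 (-6.66, SE 1.17, adjusted p = 0.0486; 7.16 and 31.5 against 75.4 and 3.24). For Mcub the fitted value was -11.4 (SE 1.99, adjusted p = 0.0486; 0.534 and 2.19 against 3.67 and 0), but the LTHSC KI libraries held 0 counts, so it is no bound on the fold. Without the 4 libraries of TMM factor under 0.8, which leaves 1 MkP KI library, none of these 7 passed, with log2 values of 4.08 for Egr1 (adjusted p = 0.215), 2.90 and 2.21 for Ppp1r15a in VF and E12 (adjusted p = 0.0611 and 0.311), -3.67 for Fcer1a (adjusted p = 0.709), -1.83 for Vim (adjusted p = 0.404) and -3.25 for Tespa1 (adjusted p = 0.627). The loss of a call there does not show that the effect was absent, and the median of the immediate-early list for the VF effect in MkP against LTHSC was 2.45 (2.26 with all libraries).

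LTHSC E12 4, preMegE KI 1, MkP KI 5 and MkP KI 6 stood apart from the other libraries of their populations, with a spread of log2 ratios of 1.27 to 1.55 against 0.254 to 0.706 in the other 20. Gene length is argued against as the whole cause, since with the length trend removed the spread was 1.02 to 1.23 and 0 of the 4 fell into the range of the others, and low depth too, since with all libraries thinned to the smallest total the spread was 1.25 to 1.55 against 0.256 to 0.696 and 0 of the 4 fell into the range of the others, although 2 of the 4 had the lowest total of their population. RNA of neutrophil and monocyte progenitors may account for part of LTHSC E12 4, where 53.8% of the list's 26 measured members (14, with Mpo at 16070 and Elane at 4376 CPM) lay above every other LTHSC library; the stem cell sort should remove such cells, and 3 members stand in other lists. It stays open in the other 3 libraries: 13 of 25 members in MkP KI 6 (52%), 7 of 25 in MkP KI 5 and 0 of 26 in preMegE KI 1 lay above every other library of the population not among the 4, with Ms4a3 raised in KI 5 and 6 (421 and 465 against at most 154 CPM), Elane in KI 6 (1980, and 1010 in KI 5, against at most 1040) and Mpo in neither (1450 and 1350 against up to 5720), and mast, basophil and eosinophil genes summed to 1134 and 1070 CPM in KI 5 and 6 against at most 327 in the other MkP libraries. LTHSC E12 4 differed from preMegE VF 1, KI 3, KI 2 and VF 2 by a chi-square per degree of freedom of 245.2 to 309.5. From the other LTHSC libraries it differed by at least 321.7, from preMegE VF 3 by 376.4 and from preMegE KI 1 by 713. In it 27 of 33 stem cell members lay below every other LTHSC library. A wrong sort or population label of LTHSC E12 4 was not tested, nor was a difference between the animals. By the same measure preMegE KI 1 differed from MkP KI 5 and KI 6 by 83.95 and 122.4, and these 2 from each other by 99.99. From the other preMegE libraries preMegE KI 1 differed by 453.5 to 907.5. MkP KI 5 and KI 6 differed from the other MkP libraries by at least 668.2 and 932.4. These 3 libraries thus lay closer to each other than to the rest of their populations. A state that they share across the 2 sorts was not tested.

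Echdc2 was at 0 to 5.21 CPM in the 9 VF libraries and at 5.53 and 1.70 in MkP KI 5 and KI 6, against 124 to 385 in the other 13. Gene length is argued against for the fall in KI 5 and 6, since 0% of 370 genes of like length and level fell as far (log2 -5.40; lowest of the others -2.36). A wrong label of both libraries stays open: of the other genes that separate the 9 VF libraries from the 13, Sva and Tjp1, 0 of 2 put both libraries on the VF side, while in a second set, chosen after those values were seen, 6 of 8 genes called between VF and E12 MkP did so (75%), and KI 4 lay nearer VF for 2 of the 8, though these genes could follow sex, since KI 5 and 6 hold Y-linked reads with little Xist, as VF 1 and 3 do, while KI 4, E12 4 and E12 5 are high in Xist with under 0.3 CPM of Y-linked genes. For Ms4a3, Rgcc, Esr1 and Tfrc both libraries lay beyond the VF mean, as seen from E12. Ms4a3 was at 421 and 465 CPM in KI 5 and 6 against means of 124 in VF and 43.5 in E12. These genes could thus also follow what sets KI 5 and 6 apart, which was not tested. Jak2 runs with the labels, at 46.6 and 36.5 CPM in KI 5 and 6 against 64.0 to 81.2 in VF MkP, though KI 4 (66.0) lies within the VF range. It does not decide the label, since no Jak2 difference passed in MkP and KI 5 and 6 stood apart from the other MkP libraries. Their log2 ratios to the MkP libraries not set aside fell with gene length (Spearman -0.349 and -0.471), which was not separated from the Jak2 level. A strain variant or linked region also stays open, since 0 of 22 expressed genes within 1 Mb separate the same libraries, which a variant in Echdc2 alone would give too, and an effect of the VF genotype or its Cre driver was not tested apart from these.

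Globin RNA was higher in all 3 LTHSC E12 libraries (Hba-a1 at 240 to 630 CPM) than in KI (5.95 to 11.8) and VF (21.7 to 34.1). More of the same globin RNA that the LTHSC KI and VF libraries hold is argued against. The ratio of Hba-a1 to Hbb-bs was 4.01 to 5.29 and lay outside the range of these 6 (0.803 to 1.17) in all 3. In MkP the ratio was 1.8 to 4.32 in KI, 2.41 to 3.63 in VF and 3.73 to 4.42 in E12. In preMegE it was 5.95 to 8.1 in KI and 4.79 to 14.5 in VF. The ratio therefore does not speak against globin RNA brought by cells of another kind. Hba-a1 was also higher in MkP E12 (61.8 to 335 CPM) than in MkP KI (5.45 to 28) and VF (13.7 to 41.7). Gene length is argued against, since Hba-a1 still passed with the length trend removed (log2 5.54, SE 0.43, adjusted p = 0.000948). Cells like preMegE stay open. With preMegE KI 1 as their source, which itself stood apart and held 1320 CPM of Hba-a1, a share of 0.182 to 0.479 would be needed. The other preMegE libraries held 118 to 191 CPM, less than LTHSC E12, so at those levels no share would reach it. The median of 50 preMegE marker genes reached at most 0.247 of the level that the share of preMegE KI 1 would bring. However, no preMegE library of the E12 line was analysed here. With 10 times the Hba-a1, the fold of E12 over KI in MkP, the medians would be 0.227 to 2.48. RNA of later erythroid cells stays open too, and expression in the E12 stem cells themselves was not tested.

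Other splits of the libraries were counted for each comparison. In LTHSC the real split was the 1 of 10 with the most genes for VF against KI (13, highest other 0), for E12 against KI (6, highest other 0) and for VF against E12 (5, highest other 0), as it was for preMegE VF against KI (1 of 10; 2 genes, highest other 0). For MkP all 10 of 10 splits gave at least as many genes as the real 0, with a highest other of 1379 for VF against KI, 1052 for E12 against KI and 0 for VF against E12. Sets of 10 splits are too few for a share under 0.05. The splits with 1379 and 1052 genes set MkP KI 5 and KI 6 with VF 3 or E12 5 against the rest, which points to a structure of the samples.

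Over all 24 libraries 24 splits were counted for each test. The real split called the most genes for MkP against LTHSC (1 of 24, 5198 genes, highest other 1). It did so too for preMegE against LTHSC (1 of 24, 6089 genes, highest other 0). This share is the smallest that 24 splits allow. The other splits mixed both populations on each side, so the difference between them added to the spread within a side. They took libraries as independent, though VF libraries of the same number may share animals. This count alone therefore does not exclude chance. Chance was not excluded either for MkP against preMegE (3 of 24, 1128 genes, highest other 3895). There the top split put preMegE KI 1, MkP KI 5 and MkP KI 6 on the same side, a structure of the samples. Nor was chance excluded for the VF effect between MkP and LTHSC (3 of 24, 2 genes, highest other 6) or the E12 effect (2 of 24, 5 genes, highest other 6). All 24 of 24 splits gave at least as many as the real 0 for the VF effect between MkP and preMegE (highest other 1979, a structure of the samples in which MkP VF faces MkP KI and preMegE KI 1 stands with MkP KI) and between preMegE and LTHSC (highest other 57, from the split that sets VF against KI in both populations at once).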

How the results depend on the processing

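The fits without genes on X and Y, without the 4 libraries of TMM factor under 0.8, with the length trend removed and with Xist as a covariate were chosen after the result was seen; the others were planned. Where a value moved, the cause was not tested. No named gene that passed in the reported fit or in an alternative had opposite directions in those fits. A change of sign where neither fit passed was not counted. Of those tested, with RLE scaling 162 stayed on their side of the threshold and 5 lost their call. Without a filter 155 stayed, 8 gained and 4 lost, and with DESeq2 149 stayed and 18 gained. With voom 148 stayed, 17 gained and 2 lost, and without the 4 libraries 148 stayed, 13 gained and 6 lost. Over the fits that left out 1 library, 1764 stayed, 15 gained and 141 lost. With thinned counts 166 stayed and 1 gained. Thinning only lowers depth, so this does not show whether more depth would add calls.

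Counts of changed genes follow in the order VF against KI, E12 against KI and VF against E12 in LTHSC, VF against KI in preMegE, then the same 3 in MkP, where the reported values are 13, 6, 5, 2, 0, 0 and 0. They were 287, 467, 185, 66, 2570, 2847 and 11 with DESeq2; 1232, 8, 17, 70, 4111, 4203 and 39 with voom; 293, 18, 13, 31, 60, 99 and 12 without the 4 libraries; and 36, 70, 30, 4, 984, 1302 and 2 in the fit over all 24 libraries. With only the 2 groups compared they were 931, 2 and 1 in LTHSC and 13 for VF against E12 in MkP. Without a filter they were 21 and 9 for the E12 comparisons in LTHSC, 9 in preMegE and 1043 for E12 against KI in MkP. Thinned counts gave 14 for E12 against KI in LTHSC, RLE gave 0 in preMegE and removal of the length trend 9, and the Xist covariate gave 3018 for VF against KI in MkP.

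From preMegE to MkP (reported 1128) the count was 1790 with DESeq2, 3851 with voom and 2708 without the 4 libraries. For the VF effect between MkP and LTHSC (reported 2) it was 4 without a filter, 121 with DESeq2, 3333 with voom, 5 with the length trend removed and 0 without the 4 libraries; between MkP and preMegE (reported 0) 21 with DESeq2 and 2234 with voom; between preMegE and LTHSC (reported 0) 11, 7 and, without the 4 libraries, 33. For the E12 effect (reported 5) it was 0 without a filter, 2050 with DESeq2, 2912 with voom, 26 with the length trend removed and 0 without the 4 libraries.

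With the replicate number as a block the count was 705 for VF against KI in LTHSC, 10 in preMegE, 9 for E12 against KI in MkP and 2279 from LTHSC to MkP. The block could not be run for the comparisons with E12 in LTHSC, for VF in MkP or for the other 3 differences of differences.

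Leaving out 1 library at a time gave 1 to 7 genes for VF against KI, 2 to 379 for E12 against KI and 1 to 306 for VF against E12 in LTHSC, with the highest values without KI 2, E12 2 and E12 2. It gave 0 to 31 in preMegE (highest without KI 1), 0 to 6738 and 0 to 6862 for VF and E12 against KI in MkP (highest without KI 4) and 0 to 0 for VF against E12. From LTHSC to MkP it gave 4461 to 6408, from LTHSC to preMegE 5179 to 6053 and from preMegE to MkP 695 (without MkP VF 1) to 1912 (without MkP KI 4). For the differences of differences it gave 2 to 2615, 0 to 78 and 0 to 0 for VF and 0 to 4532 for E12, with each highest value above 0 without MkP KI 4. The lowest values for VF against KI in LTHSC were without VF 1, 2 or 3. Where 1 library was left in a group, it was assumed to vary like the others.

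Of 138 list calls 10 remained with an estimated correlation. By fry 53 lists were called, 43 of them among the 138. Without the 4 libraries 121 were called, with 93 of the 138 kept in the same direction, while 39 lost their call and 6 changed direction: oxidative phosphorylation (adjusted p = 2.96e-09) and histone genes (0.00859) for VF against KI in MkP, the same lists for E12 against KI (7.2e-07 and 0.00233), and oxidative phosphorylation for the VF effect between MkP and LTHSC (0.0122) and MkP and preMegE (0.00512). None of these 6 held with an estimated correlation (adjusted p = 0.605 to 0.973). The log2 difference of mean Jak2 without TMM scaling was 0.93 for VF against KI in preMegE and 1.20 and 0.79 for VF and E12 against KI in MkP (0.65, 0.54 and 0.10 with it).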

Other observations

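The gene lists in this part belong to planned comparisons and were picked for description after the data were seen, and the sex markers and Malat1 were looked at only then. Genes of the respiratory chain and the histone genes rose with the steps out of LTHSC. From LTHSC to MkP 58 of 71 nuclear oxidative phosphorylation genes rose (63 adjusted over the list alone, camera adjusted p = 1.45e-10; adjusted p = 0.377 with an estimated correlation), and 18 of 19 histone genes rose over all genes and over the list alone (camera adjusted p = 3.45e-08; adjusted p = 0.264 with an estimated correlation). From LTHSC to preMegE 69 of 71 and 18 of 19 rose, with 1 histone gene lower, over all genes and over the list alone (adjusted p = 0.256 with an estimated correlation for both). MkP KI 5, MkP KI 6, preMegE KI 1 and LTHSC E12 4, which stand apart, are in these fits.

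Mast, basophil and eosinophil genes also differed between populations. From LTHSC to MkP 8 of 16 rose and 1 fell over all genes and over the list alone (median log2 2.23, camera adjusted p = 0.00157; adjusted p = 0.264 with an estimated correlation), and from LTHSC to preMegE 7 rose and 1 fell (median 3.77, camera adjusted p = 0.000469; adjusted p = 0.181 with an estimated correlation), the same counts adjusted over the list alone. Neutrophil and monocyte genes moved between LTHSC and preMegE, 14 of 27 higher and 2 lower over all genes and over the list alone (camera adjusted p = 0.000469; adjusted p = 0.35 with an estimated correlation).

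Xist, the RNA that silences an X chromosome, was at 2719, 2004 and 2061 CPM in MkP KI 4, E12 4 and E12 5, which held under 0.3 CPM of Y-linked genes. These and the following Xist and Y-linked values are CPM without TMM scaling. The VF 2 libraries of LTHSC, preMegE and MkP held both Xist (533, 309 and 598 CPM) and Y-linked reads (186, 53.8 and 128 CPM), as did MkP E12 2 (869 and 105 CPM). No other VF library had Xist above 5 CPM, which points to the same animals or pool behind the VF 2 libraries of the 3 populations. LTHSC E12 2 and E12 4 held 9.59 and 9.35 CPM of Xist and 257 and 64.4 CPM of Y-linked genes. By these markers they differed from the MkP libraries of the same number, so the E12 numbers may not mark the same animals in LTHSC and MkP. This does not exclude a shared animal, since MkP E12 2 holds both kinds of reads and the label of LTHSC E12 4 was not tested. Malat1, a nuclear RNA, was at 18680, 8757 and 12870 CPM in MkP KI 5, MkP KI 6 and preMegE KI 1, and the 50 most abundant genes held 22.5%, 22.2% and 20.9% of their counts.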
